A study of Mus musculus with 6 samples.

How the data were processed

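Small RNA was sequenced from 6 libraries labelled as Mes23.5, a dopaminergic cell line made by fusing mouse neuroblastoma with rat midbrain cells. All were labelled as stimulated with LPS, a bacterial cell wall component, for 24 h. The labels put 3 libraries in each group: cells given vesicles of microglia that overexpress the transcription factor SIX2 (SIX2_EV), and cells given vesicles of control microglia (control_EV). The growth protocol in the labels names BV2, a mouse microglial line, in place of Mes23.5, so the cell of origin is given here only as labelled. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

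Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with the TruSeq small RNA kit, and the authors removed adapter dimers, junk, low-complexity reads, common RNA families (ribosomal, transfer, small nuclear and small nucleolar RNA) and repeats with ACGT101-miR. The genome build, the miRBase release and the mapping settings are not given in the sources used here. The deposited table gives, for each miRNA sequence and locus, estimated counts that were split over loci and need not be whole, per the file headers (raw). Its other columns hold the authors' normalized signal, which equals the counts times 1 factor per library, from 0.2267 in the third control_EV library to 3.3986 in the second SIX2_EV library. How the authors chose these factors is not given in the sources used here.

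The table has 823 rows with 724 distinct sequences. Rows with the same name and sequence were summed, which gave 756 features, and the sums were rounded to whole reads. Of the sequences, 29 stood under several names, and each such name is its own feature. Within a tolerance of 0.05, 89.8% of feature values above 0 were whole. Of 2410 values above 0 per sequence and library, 31 were under 5 and 169 were equal to 5, so the table appears to list a sequence in a library only from about 5 reads. A value of 0 therefore means listed at 0 and no limit was drawn from a count of 0. Where all libraries of a group were at 0, the fold was bounded against a floor of 5 reads per library. Many conserved miRNAs carry rat names (rno) although they were placed on the mouse genome. Names ending in p5 or p3 after a hairpin mark other sequences of that hairpin, and PC marks predicted sequences with no miRBase name. Suffixes such as L+4R-1 mark isoforms whose left or right end differs from the annotated miRNA, and names are printed here without them. Positions are printed as deposited. Of 118 mouse-named rows matched to a GRCm38 gene table, all 118 lay on the same chromosome but only 6 overlapped the table's position, so the deposited build is another one and was not mixed with GRCm38. Deposited sequences with a mouse position were matched to GENCODE M21 transcripts by sequence alone.

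Deposited reads per library ranged from 179621 to 421279. Intervals for shares of a single library are Wilson intervals at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.

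The groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts, with TMM scaling, the filterByExpr filter, no block and Benjamini-Hochberg adjustment at 0.05. The filter left 319 of 756 features. CPM values are reads scaled to the TMM effective library. miRNA lists were tested with camera (limma 3.58.1) on voom values at a preset correlation of 0.01, and again with an estimated correlation. Single values were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 libraries is 0.1. Before the data were examined, the groups, this test, the main alternatives, 21 lists with 243 distinct miRNAs and the rule for named features were fixed. Of these miRNAs, 134 were matched to a deposited name, and 10 more were listed under a rat name with another letter, a copy number or no arm, such as miR-9a-5p, miR-17-1-3p and miR-182. The plan spoke of mouse rows. Because conserved miRNAs carried rat names, members were matched without regard to species prefix or isoform suffix, by their most abundant feature with a mouse position, and the suspected fragments of other RNAs by hairpin. The main list tests use the 134, and an alternative added after the data were seen also takes those under variant names, except miR-486b-5p, whose sequence was already in its list.

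The rule named miR-3470b and miR-3470a, features past the threshold with no overlap between groups and a mean of at least 10 CPM, the 10 most abundant features, and for each list the members with the smallest p and the most abundant one. If fewer than 10 features passed, those with the smallest unadjusted p were to be added up to 10, as happened here. The features that did not pass are given with their values.

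The edgeR procedure was tested on simulated counts with 200 of 756 features changed. At the spread of these libraries it recovered 0% of tested features changed 2-fold, 13.8% of those changed 4-fold and 54.3% of those changed 16-fold, and it called 0 of 197 unchanged features. At a dispersion of 0.05 it recovered 78.3%, 97.1% and 100% of these, and called 5 of 223 unchanged features. The 16-fold changes and the low dispersion were added to the simulation after a first version had recovered few features.

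Alternatives were DESeq2 1.42.0, total counts, upper quartile scaling, other filters, limma-voom, the authors' normalized signal, a replicate block, leaving out each library, and other ways of summing features. Settings for zeros, for features with a mouse hairpin, for sums by sequence, for an estimated correlation and for the replicates that stood apart were added after the file had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.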

Results

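Small RNA libraries from LPS-stimulated cells labelled Mes23.5 were compared between 3 libraries given vesicles of SIX2-overexpressing microglia (SIX2_EV) and 3 given vesicles of control microglia (control_EV). Mes23.5 is a dopaminergic cell line, and extracellular vesicles are membrane-bound particles that carry RNA between cells. The question in the series title is whether vesicles bring miR-3470b to dopaminergic cells. The deposited reads numbered 179621, 232635 and 184208 in the SIX2_EV libraries and 257628, 253037 and 421279 in the control_EV libraries. Between 276 and 419 features were above 0 in the SIX2_EV libraries and between 439 and 680 in the control_EV libraries. No pair of replicates agreed within counting error (chi-square of at least 68.7 per degree of freedom), a comparison that covers counting error only, so each library was counted as its own.

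The first comparison asked what kinds of RNA the reads came from. Mature miRNA names with a mouse hairpin took 17.8% ± 13.4 of reads in SIX2_EV and 53.02% ± 19.9 in control_EV (SD, n = 3). Other sequences of named hairpins took 65.3% ± 7.48 and 39.0% ± 16.9 (SD, n = 3). The 10 most abundant features took 76.6% ± 9.24 of reads in SIX2_EV and 51.5% ± 13.5 in control_EV (SD, n = 3). By mean CPM over all 6 libraries the most abundant was a cattle-named sequence, bta-mir-2887-2-p5, which in control_EV alone stood behind bta-mir-2904-3-p3 and mir-6240-p5. It was placed on chromosome 9 at 56130999 to 56131055 and had 64159, 82684 and 19879 reads in SIX2_EV and 37618, 15615 and 2733 in control_EV. Cattle names took 48.8% ± 19.0 and 22.4% ± 17.7 of reads (SD, n = 3). A cattle name alone does not mark cattle RNA. The sequence of bta-mir-2887-2-p5 occurs without mismatch in 4 mouse GENCODE M21 entries annotated as miRNA. By contrast, bta-mir-2904-3-p3 and bta-miR-11987 matched no small non-coding entry. Hairpins listed beforehand as suspected fragments of other RNAs, led by mir-6240 and mir-6236, took 24.4% ± 0.982 and 14.99% ± 6.34 (SD, n = 3), and their origin was not mapped.

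These shares differed by library as well as by group. The mature miRNA share was 13.9% (Wilson interval 13.72 to 14.04), 6.78% (6.68 to 6.89) and 32.65% (32.4 to 32.9) in SIX2_EV, and 31.5% (31.3 to 31.7), 56.7% (56.5 to 56.9) and 70.8% (70.7 to 71.0) in control_EV. The groups overlapped in the mature share, with an exact two-sided permutation p of 0.2. They did not overlap in the share of the 10 most abundant features, with a p of 0.1, the smallest that 3 against 3 libraries allow (0.246 for both after Benjamini-Hochberg adjustment over 16 shares). The gap was narrow, with 65.97% in the third SIX2_EV library and 65.1% in the first control_EV library. In the shares of the 20 and of the 50 most abundant features the groups overlapped, with a permutation p of 0.2 for each. In replicates 1 and 2 alone, the mean mature share was 10.3% in SIX2_EV and 44.1% in control_EV. Sequences named mir-1285 that match 7SL RNA, the RNA of the signal recognition particle, took 7.94% and 7.48% of reads in the third SIX2_EV and control_EV libraries. They took at most 0.447% in any other library, so the third library of each group stood apart.

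**Figure D1:**
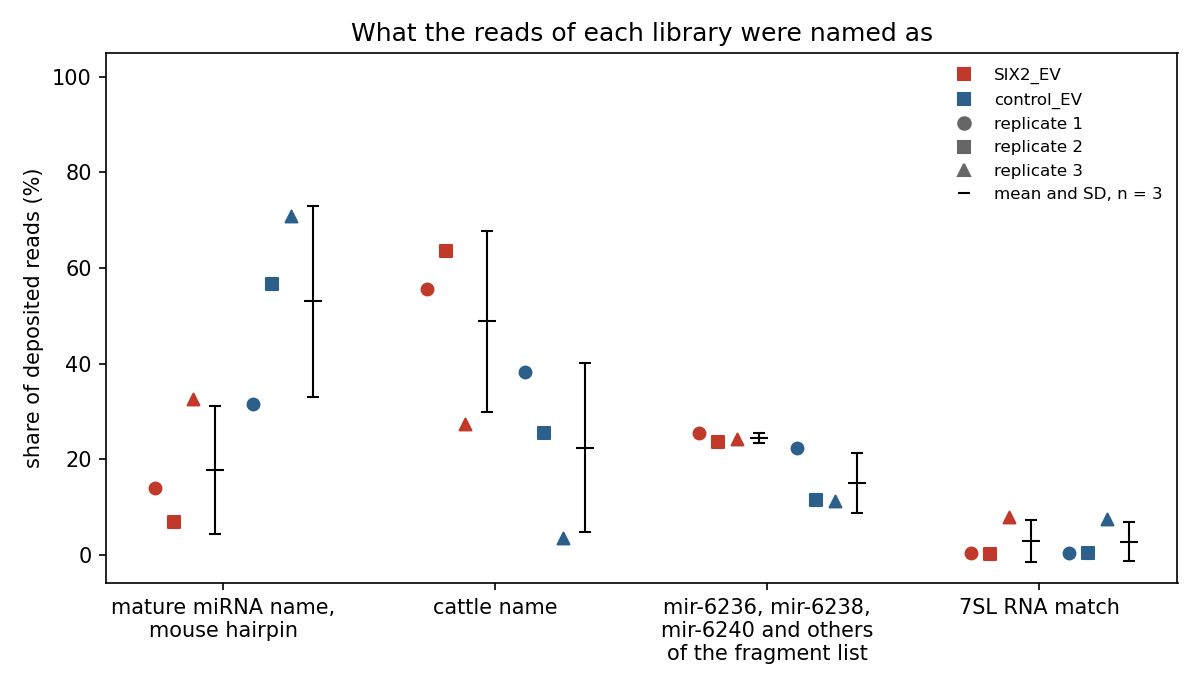
Share of deposited reads (%) by kind of name in each library, with SIX2_EV in red and control_EV in blue, a marker shape per replicate, and black bars for the mean and SD (n = 3). Mature miRNA names took 17.8% of reads on average in SIX2_EV and 53.02% in control_EV, and the 7SL match was high only in replicate 3 of both groups.

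The second comparison was about miR-3470b, the miRNA in the series title. Its level was lower in each SIX2_EV library than in any control_EV library, with 0, 0 and 254.6 CPM in the SIX2_EV libraries and 372.9, 410.4 and 379.2 CPM in the control_EV libraries. The means were 84.9 ± 147 and 387.5 ± 20.1 CPM (SD, n = 3). These values came from 0, 0 and 56 reads against 102, 164 and 424 reads. The only feature matched to miR-3470b carries the isoform suffix L+4R-1, so these are reads of a variant with shifted ends. No feature with the annotated ends of miR-3470b was matched. The deposited sequence, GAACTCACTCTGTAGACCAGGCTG, was placed on chromosome 16 at 43834215 to 43834340 within the mmu-mir-3470b hairpin, in a build that is not named. The same 24 bases occur in GENCODE M21 transcripts of 983 genes, counted on either strand. Transcripts that hold only the reverse complement would not give this read, so 983 may overstate the possible sources. Among small non-coding transcripts, 41 entries hold the bases on the same strand, so reads of other transcripts could not be told from those of the hairpin.

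The difference did not pass the test, with a log2 fold change of -2.11 (SE 1.62) and an adjusted p of 0.641 by edgeR's quasi-likelihood test. All 3 SIX2_EV libraries lay below all 3 control_EV libraries, and the exact permutation p was 0.1, the smallest possible. In replicates 1 and 2, miR-3470b was at least 6.66-fold lower in SIX2_EV against a floor of 5 reads per library, and in replicate 3 it was 254.6 against 379.2 CPM. Without SIX2_EV replicate 3 the adjusted p was 0.102 by edgeR. The other sequence of the same hairpin, mir-3470b-p3, had a log2 fold change of 1.51 with TMM (adjusted p 0.436 by edgeR and 0.0341 by DESeq2) but of 0.22 with total counts, from 24, 21 and 44 reads against 29, 40 and 52, so its size rests on the scaling. miR-3470a had 35.6 ± 31.3 CPM in SIX2_EV and 104.3 ± 27.5 CPM in control_EV (SD, n = 3; log2 fold change -1.48, adjusted p 0.638 by edgeR).

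**Figure D2:**
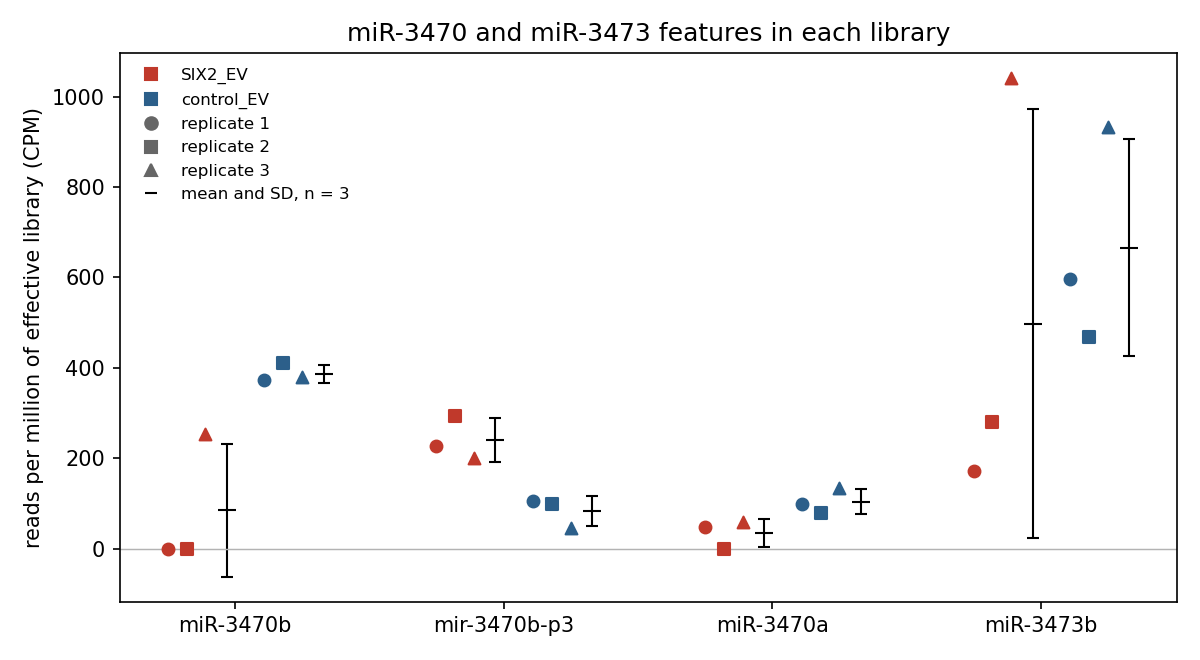
CPM of miR-3470b, mir-3470b-p3, miR-3470a and miR-3473b in each library, with SIX2_EV in red and control_EV in blue, a marker shape per replicate, and black bars for the mean and SD (n = 3). miR-3470b was listed at 0 in 2 SIX2_EV libraries and stood at 254.6 CPM in the third, below the 3 controls, while mir-3470b-p3 lay above the controls in each SIX2_EV library at this TMM scaling (log2 fold change 0.22 with total counts).

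The third comparison covered all miRNAs and other deposited sequences. No feature passed the threshold. The smallest unadjusted p belonged to miR-872-5p, listed at 0 in every SIX2_EV library and at 138 ± 53.5 CPM in control_EV (SD, n = 3), which makes it at least 2.95-fold lower. Among positive values were those of other sequences of named hairpins: mir-6240-p3, from a hairpin on the list of suspected fragments, had 110180 ± 54672 CPM in SIX2_EV and 14994 ± 10324 in control_EV (log2 fold change 2.88, SE 0.86), and the horse-named mir-615-p5 had 1205 ± 1084 and 83.0 ± 64.6 CPM (3.87, SE 0.94; SD, n = 3 for both). Their sizes rest on the scaling, with log2 fold changes of 1.44 and 2.20 with total counts. miR-669o-3p had 235.0 ± 171 CPM in SIX2_EV and 895 ± 140 CPM in control_EV (SD, n = 3; log2 fold change -1.91, SE 0.55, or -2.98 with total counts). The most abundant mature miRNA with a mouse hairpin, miR-21-5p, had 49067 ± 14721 and 58273 ± 7012 CPM (SD, n = 3; log2 fold change -0.25, SE 0.56).

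By edgeR's quasi-likelihood test, 0 of 319 features passed an adjusted p of 0.05, with a smallest adjusted p of 0.361. At an unadjusted p under 0.05 there were 39 features, 18 higher and 21 lower in SIX2_EV. In replicates 1 and 2 alone 0 passed and 96 had an unadjusted p under 0.05. limma-voom called 0, with 62 at an unadjusted p under 0.05, and DESeq2 called 20 features, 13 higher and 7 lower. The 13 higher by DESeq2 were mostly sequences named for other species, such as bta-miR-11987, and other sequences of mouse hairpins, such as mir-6240-p3 and mir-6236-p5. The 7 lower were miR-872-5p, miR-18a-3p, miR-466f-3p, miR-669o-3p, PC-5p-69247_39 and, named after their values were seen, miR-501-3p and miR-140-3p. Among the 10 smallest unadjusted p in edgeR were also the predicted PC-3p-7123_1336 and the human-named miR-1268a, with log2 fold changes of 3.18 (SE 0.75) and 4.43 (SE 1.19), or 2.24 and 2.93 with total counts. miR-18a-3p, miR-669d-5p, PC-5p-54673_58 and PC-5p-69247_39, also among them, were listed at 0 in all SIX2_EV libraries and at mean control levels of 34.1 to 54.1 CPM, close to the 46.8 CPM that 5 reads are worth there. miR-1195, chosen after its values were seen, was listed at 0 in all SIX2_EV libraries and had 15, 17 and 652 reads in the controls, at least 4.85-fold lower, but at least 1.04-fold lower without control_EV replicate 3. The groups did not overlap for 73 features (22.9%), 54 lower and 19 higher in SIX2_EV. For a single feature the chance is 10%. The features share the same libraries and scaling, so the share can vary widely between splits and is no test of an excess.

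The median log2 fold change of all tested features was -0.30 with TMM, -1.54 with total counts and -0.06 with zeros set to 4, and list medians are relative to these. With total counts, 4 features were higher and 32 lower at an unadjusted p under 0.05.

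The fourth comparison grouped miRNAs by the lists fixed beforehand. The Sfmbt2 cluster, a large rodent-specific group of miRNAs in an intron of Sfmbt2, fell in SIX2_EV as a list at the preset correlation: 10 of 11 tested members had negative values, with a median log2 fold change of -1.29 and an adjusted p of 0.0432 by camera. It did not pass with an estimated correlation (adjusted p = 0.675 with an estimated correlation). Members with the smallest p were miR-669d-5p and miR-466f-3p, the latter at 35.7 ± 31.1 CPM in SIX2_EV and 171 ± 12.6 CPM in control_EV (SD, n = 3). The most abundant, miR-669c-5p, was at 3631 ± 3079 and 3709 ± 1613 CPM (SD, n = 3). The list's median moved with the values at 0: it was -1.10 with miR-669d-5p, at 0 in SIX2_EV, set to its bound, -0.40 with zeros set to 4 (7 of 11 negative) and -6.46 without SIX2_EV replicate 3, which is no measure of size.

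The miR-17-92 cluster and its paralogs, which promote proliferation, had negative values for all 10 tested members under TMM (9 of 10 with DESeq2), with a median of -0.80, but the list did not pass (adjusted p 0.0668 by camera, 0.675 with an estimated correlation). With miR-17-3p, deposited under a variant rat name, 11 of 11 were negative (median -0.72, adjusted p 0.105). miR-17-5p had 3281 ± 940 and 6532 ± 1944 CPM, and miR-20a-5p 6189 ± 1341 and 12577 ± 4926 CPM in SIX2_EV and control_EV (SD, n = 3). Suspected fragments of other RNAs were positive for 3 of 3 tested members with TMM, with a median of 2.36 and an adjusted p of 0.0668 by camera (0.675 with an estimated correlation). The median was 0.86 with total counts, and 0.45 with 2 of 3 positive for the third SIX2_EV library against all controls. The miR-17-92 list passed with zeros set to 4 and without SIX2_EV replicate 1 or 2, the suspected fragments without SIX2_EV replicate 3 or control_EV replicate 1, and both with no filter or a filter of 10 CPM. mir-6236-p5 had 113870 ± 69624 CPM in SIX2_EV and 22123 ± 14994 in control_EV (SD, n = 3). In each of these lists 0 members passed by edgeR over all features, and 0 when adjusted over the list alone, while DESeq2 called miR-466f-3p and mir-6236-p5 (adjusted p 0.0351 for both). The Sfmbt2 call was also lost with total counts, upper quartile scaling, the authors' normalized signal, sums by mature name, features with a mouse hairpin only or zeros set to 4, and without control_EV replicate 2 or control_EV replicate 3. The SIX2_EV libraries, with their lower mature miRNA share, had few reads behind several Sfmbt2 members, such as 6, 0 and 11 for miR-466f-3p.

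**Figure D3:**
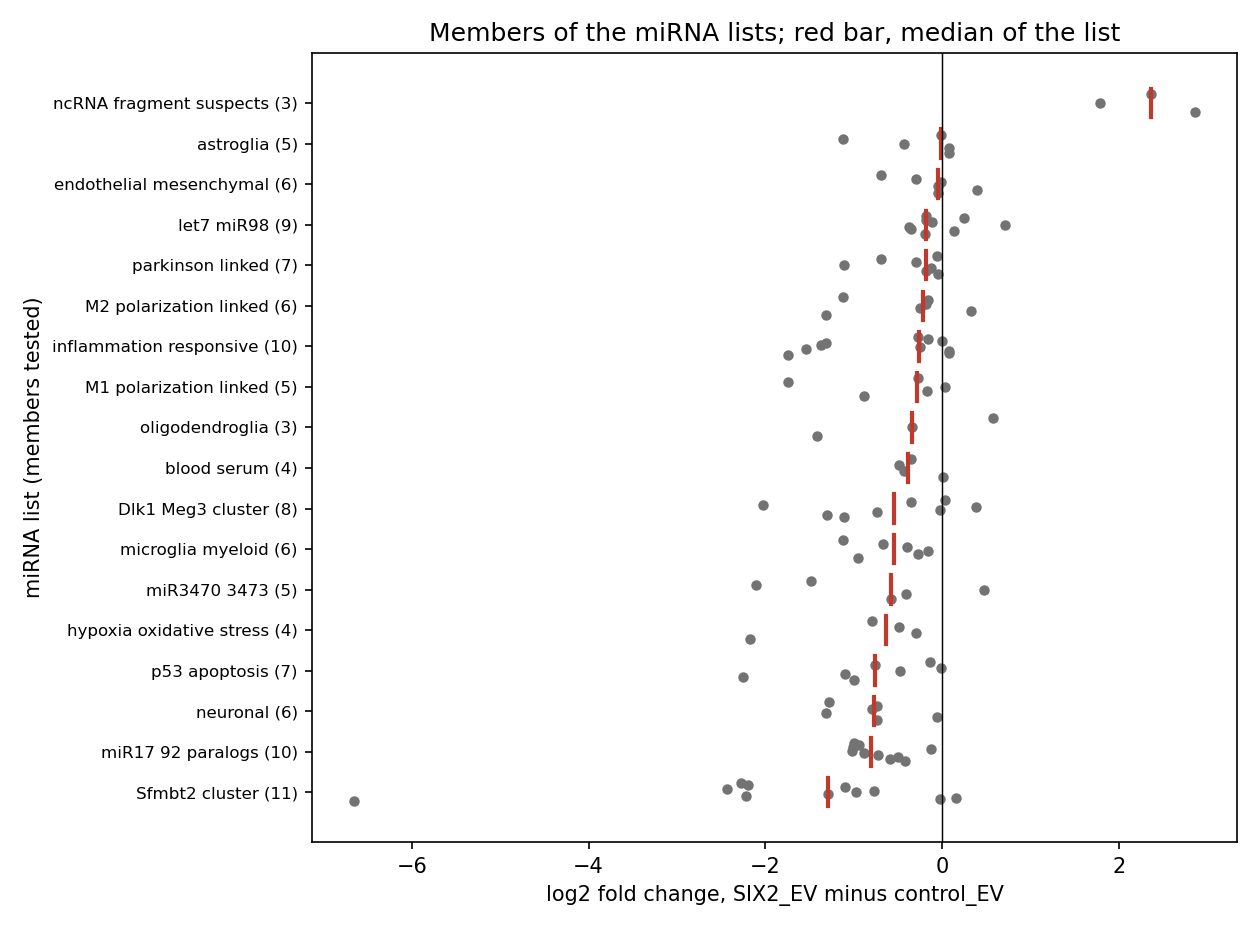
Log2 fold change of SIX2_EV minus control_EV for each tested member (grey points) of the 18 lists with at least 3 tested members, with the median of each list as a red bar. The medians run from -1.29 for the Sfmbt2 cluster to 2.36 for suspected fragments.

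The fifth comparison asked which cell types' miRNAs the libraries held. Members of the myeloid list stood at very different levels. miR-146a-5p, induced by inflammatory signals, had 27811 ± 2051 CPM in SIX2_EV and 31159 ± 11546 in control_EV, and miR-142-5p, a miRNA of blood cells, had 3026 ± 642 and 3991 ± 181 CPM (SD, n = 3). miR-223-3p, miR-155-5p and miR-150-5p, named after their values were seen, had 92.4 ± 160.1, 173 ± 40.4 and 35.7 ± 31.1 CPM in SIX2_EV and 209 ± 176, 211 ± 27.6 and 71.9 ± 25.3 CPM in control_EV (SD, n = 3). The rat-named miR-342-3p and miR-342-5p were each listed in 1 library. A cattle-named miR-342 that matches mouse Mir342 with 1 mismatch was tested but was not matched to the list. Named after its values were seen, it had a log2 fold change of 0.12 with TMM, -0.61 in replicates 1 and 2 alone and -0.88 with total counts. Of 19 neuronal miRNAs, 8 were listed and 6 tested. miR-124-3p was not among the deposited rows, and miR-9-5p and miR-218-5p, both named after their values were seen, had 7 and 21 reads in 1 control_EV library each. The most abundant was miR-7a-5p at 2177 ± 372 and 2271 ± 663 CPM, and miR-128-3p had 101 ± 25.0 and 244 ± 52.9 CPM (SD, n = 3). miR-451-5p, a red blood cell miRNA, had 13930 ± 4039 and 17730 ± 11072 CPM (SD, n = 3).

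None of these cell type lists passed by camera. The myeloid list had 6 of 6 tested members negative with a median of -0.54 (adjusted p 0.593), the neuronal list 6 of 6 with -0.77 (0.371; 5 of 6 for both lists with DESeq2), and the blood and serum list 3 of 4 with -0.39 (0.734). The oligodendroglial list had a median of -0.34 (adjusted p 0.69). The astroglial and endothelial or mesenchymal lists had medians of -0.01 and -0.05 (adjusted p 0.69 and 0.734), with a positive direction in camera and positive medians with DESeq2 and with zeros set to 4. Epithelial and muscle lists had 1 and 0 tested members. In each of these lists 0 members passed by edgeR over all features, and 0 when adjusted over the list alone. In replicates 1 and 2 alone the myeloid median was -0.54 and the neuronal median -1.01, while the neuronal median was 0.29 for the third SIX2_EV library against all controls. With zeros set to 4 the myeloid median was -0.32 (6 of 6 negative) and the neuronal median -0.27 (3 of 6). The lower mature miRNA share of SIX2_EV libraries stood beside all of these lists.

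The sixth comparison covered inflammation, polarization of microglia, which is the state between inflammatory (M1) and repair (M2) programs, and stress. Here too no list passed with TMM and the filter used. Among M1-linked miRNAs, miR-101a-3p had 2404 ± 262 CPM in SIX2_EV and 4434 ± 1115 in control_EV, with a log2 fold change of -0.88 (SE 0.27) and an adjusted p of 0.368 by edgeR. A feature named miR-101b-3p had the same log2 fold change in each set of libraries, so the reads of this sequence appear to be split over both names. Among M2-linked miRNAs, miR-132-3p, also a neuronal and inflammation-responsive miRNA, had 139 ± 15.5 and 346 ± 93.3 CPM (log2 fold change -1.31, SE 0.50). miR-210-3p, the main miRNA induced by hypoxia, had 646 ± 110 and 1120 ± 157 CPM (log2 fold change -0.80, SE 0.26; SD, n = 3 for each).

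The M1-linked list had a median of -0.28 (4 of 5 negative, adjusted p 0.69 by camera), the M2-linked list -0.22 (5 of 6, 0.734) and the inflammation-responsive list -0.26 (8 of 10, or 6 of 10 with DESeq2, 0.681). The hypoxia and oxidative stress list had a median of -0.64 (4 of 4 negative, adjusted p 0.19), or -0.48 (5 of 5, 0.392) with miR-182-5p under its variant rat name. The p53 and apoptosis list had a median of -0.76 (7 of 7 negative, or 5 of 7 with DESeq2, adjusted p 0.371 by camera, 0.675 with an estimated correlation). At the preset correlation it passed with zeros set to 4 (median -0.67, 6 of 7 negative). Parkinson-linked miRNAs had a median of -0.18 (7 of 7, or 4 of 7 with DESeq2, 0.734), the Dlk1-Meg3 cluster -0.54 (6 of 8, 0.593) but 0.13 with zeros set to 4, and the miR-3470 and miR-3473 list -0.58 (4 of 5, 0.593) but 0.49 for the third SIX2_EV library against all controls. The let-7 and miR-98 list had a median of -0.18 (6 of 9, 0.734), with a positive direction in camera and a median of 0.16 in replicates 1 and 2 alone. The miR-183 cluster had 3 tested members with miR-182-5p under that name (2 negative, median -0.05, adjusted p 0.838, with a positive direction in camera and medians of 0.11 with DESeq2 and 0.03 with zeros set to 4). In each of these lists 0 members passed by edgeR over all features, and 0 when adjusted over the list alone, and with total counts every tested member of these lists was negative.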

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

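Settings for zeros, mouse hairpins, sums by sequence, list members under variant rat names, an estimated correlation and replicates 1 and 2 alone were chosen after seeing the data. The count of features past the threshold was 0 in every edgeR or limma setting and 20 with DESeq2, whose cause was not tested. Leaving out 1 library gave 0 calls each time, with 9 (without control_EV replicate 2) to 95 (without SIX2_EV replicate 3) features at an unadjusted p under 0.05, against 39. In replicates 1 and 2 alone 0 features passed, with 96 at an unadjusted p under 0.05. miR-3470b was negative in each setting and passed in none, with log2 fold changes from -10.24 without SIX2_EV replicate 3 to -0.66 for the third SIX2_EV library against all controls, and -1.63 with zeros set to 4. The first of these is set by values at 0 and is no measure of size. The number of lists past the threshold was 1 and went to 0 with total counts, upper quartile scaling, the authors' normalized signal at each pseudocount, sums by mature name, features with a mouse hairpin only and an estimated correlation. It went to 3 with no filter or a filter of 10 CPM (the miR-17-92 list and the suspected fragments joined), and to 2 with zeros set to 4 (miR-17-92 and p53 lists); the cause was not tested. Leaving out 1 library gave 0 to 2 lists. With list members under variant rat names it was 1 (Sfmbt2 cluster, adjusted p 0.0456, or adjusted p 0.764 with an estimated correlation). The 10 most abundant features took 25.1 percentage points more in SIX2_EV, or 16.1 to 31.9 with 1 library left out, and the difference was 10.5 points for the 50 most abundant, which take most reads in both groups. The myeloid median stayed negative, from -0.66 to -0.28 with 1 library left out. miR-669d-5p and PC-5p-54673_58 turned to 0.10 and 0.07 with zeros set to 4, since their values in SIX2_EV were 0. With the replicate number as a block 0 features passed and 0 lists were called. Same-numbered libraries correlated in their deviations at 0.209, 0.067 and 0.673, so the numbers were not taken to pair the libraries. Not every library correlated best with its own number. The third library stood apart in both groups, but a factor for the third libraries was not fitted. Their difference stays in the spread of the main test. Since values under about 5 reads appear not to be listed, SIX2_EV replicate 2 is limited most. Its TMM effective library was 71426 reads against 1118214 in control_EV replicate 3, from 232635 and 421279 deposited reads. The TMM factors were 0.308 and 2.729, so this limit reflects the scaling as well as depth. The split into groups called 0 features with edgeR and the highest other 0, so 10 of 10 splits are as large by construction and the count says nothing about chance. For lists the real value was 1 and the highest other 1, with 3 of 10 splits as large, and 10 splits are too few for a share under 0.05. Joining SIX2_EV replicates 1 and 2 with control_EV replicate 1 gave 42 features at an unadjusted p under 0.05, against 39. Voom values were the main input of the list tests, so limma-voom gave no separate list result.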

Other observations

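All tests in this part were chosen after the result was seen. Transcripts of many genes hold the sequences of several rodent miRNAs in the table, on either strand. Of 384 mature features with a mouse hairpin, 16 occur in GENCODE M21 transcripts of more than 10 genes, against a median of 1 gene. These counts take both strands together, and only transcripts with the sequence on the same strand would give the read. They include miR-3470a, miR-3470b, miR-3473b, miR-1195 and members of the miR-466, miR-467 and miR-669 families. Of the 12 that were tested, 10 had negative values in SIX2_EV, with a median log2 fold change of -1.03, against -0.30 for all tested features. No list test was run on them. Both features with the highest share of 7SL-matching reads, mir-1285-p3 and mir-1285-p5, had log2 fold changes of 1.23 with TMM and of 0.06 and -0.15 with total counts, with no call.

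The smaller share of mature miRNA reads in SIX2_EV is the first pattern. All 54 mature miRNA features with a mean of at least 1000 CPM had negative total-count log2 fold changes, from -2.42 to -1.06 with a median of -1.56. Some of these features share a sequence under different names. Of the 54, 100% lay within 1 of that median, so a factor common to these features may account for most of the pattern. Each value compares the groups, so it cannot show a factor per library. The joint fall of these features also restates the lower mature share. Shares of reads cannot tell whether a common factor came from more reads of abundant fragments, whose origin was not mapped, or from less miRNA. A fragment load that varies between preparations and one set by the treatment cannot be told apart with 3 against 3 libraries, where the share had an exact permutation p of 0.2. Treatment stays open and untested.

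The second pattern is miR-3470b at 0 in 2 of 3 SIX2_EV libraries. The values argue against low depth alone. At the lowest control level 39.2 and 26.6 reads would be expected there (chance of under 5 by Poisson counting 1.02e-12 and 6.62e-08). Of 61 mature miRNA features at 0.5 to 2 times its control level only 5 (8.2%) were at 0 in both libraries, among them miR-1195, miR-212-3p and miR-223-3p. miR-1195 and miR-223-3p reached that level only through control_EV replicate 3. Of the 61, 4 occur in transcripts of more than 10 genes on either strand, and 2 of these were among the 5. With the spread fitted to miR-3470b itself, which holds its zeros in these libraries, the chances of under 5 reads were 0.265 and 0.32. Spread between libraries therefore stays open. Reads of transcripts with the same repeat may also contribute, since the sequence occurs in transcripts of 983 genes. That count takes both strands together, and only transcripts with the sequence on the same strand would give this read. A lower level after SIX2_EV treatment stays open too, with an exact permutation p of 0.1, the smallest possible.

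The third pattern is that the sum of miR-142 and miR-223 stood above the neuronal list in libraries labelled as a dopaminergic line. Their reads, mostly of miR-142, exceeded those of the 8 listed neuronal miRNAs in each library, by 1.38 to 2.01 times. This ratio restates the pattern and so cannot tell its source. RNA of microglia or of their vesicles is a hypothesis that the BV2 growth protocol makes worth checking. However, miR-142 is a miRNA of blood cells in general. The red blood cell miRNA miR-451-5p stood above miR-142-5p in each library, with means of 13930 against 3026 CPM in SIX2_EV and 17730 against 3991 CPM in control_EV. Of the myeloid list 3 members, and of the neuronal list 6, are also in another list, and how many the labelled line expresses was not known here. Reads under hairpins of cattle, goat or sheep only, without a mouse position, were found in 5 libraries, up to 0.172% of reads. They were led by bta-miR-2284x and bta-miR-342. Sequences without a mouse position were not matched to mouse transcripts. Another cattle-named form of miR-342 matches mouse Mir342 with 1 mismatch, so these reads may include mouse miRNAs. RNA of bovine serum may also be present, and reads carried over from other libraries were not tested. No deposited name without a mouse position had rat hairpins only (0 features), and no biological explanation by group was tested.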
